A study of Tachysurus vachellii with 6 samples.

How the data were processed

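Gill RNA of 6 pooled libraries was analysed from the table that the authors deposited, with no reads. Per the labels' protocols, total RNA was extracted from 9 fish per group after 96 h, mixed in sets of 3 fish, enriched with oligo-dT beads and sequenced as paired reads on an Illumina NovaSeq instrument. The pools are the replicates, so all errors and p-values describe the spread between pools and not between single fish. Poly(A) selection captures polyadenylated transcripts, and the 1208 transfer RNA genes in the table are not measured well by it.

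Per the submitters' processing notes, cutadapt 1.9 and HISAT were used; the counter, the FPKM program, the strand setting, the genome build and the annotation are not given in the sources used here. Per the file headers, the deposited values are counts and FPKM for each gene and library. The counts are whole numbers with different totals, 44762764 to 55016223 per library. Counts of 1 to 3 were rarer than larger ones (134 to 198 genes per library, against 174 to 369 genes with exactly 4 counts), and of the counts from 1 to 20, 56.0% to 63.0% per library were even. Whether a count stands for a read, a read pair or an estimate from coverage, and whether a minimum was set, is not given in the sources used here. If both reads of a pair were counted, fewer independent fragments lie behind the totals than they show, and the counting precision is lower. The deposited FPKM are counts scaled to transcript length and library total, and a gene with a count of 0 is listed at 0.0001. Coordinates are given as in the deposited table, which names scaffolds of an assembly whose build is not given in the sources used here, with no exon structure. Gene symbols were present for 11153 genes, and the other 17135 carry LOC identifiers with descriptions taken from similar proteins of other fishes, so a description is a likeness and not an identity. Without a stated strand setting, overlapping genes on opposite strands cannot be told apart. Some annotation cells, 254 in all, were not used here.

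Samples were grouped by the treatment in their labels, and columns were matched to samples by the group code and number in the titles. The comparison of all 3 hypoxia with all 3 normoxia libraries was fitted with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) on the counts with TMM scaling, in R 4.3.3. TMM factors ran from 0.867 for hypoxia replicate 1 to 1.08 for normoxia replicate 2. The design written before the data were examined foresaw limma on log2(FPKM + 1) for a table of FPKM alone and the count test where counts are present. The count test is therefore the main result and limma 3.58.1 an alternative. Genes with an FPKM of at least 1 in at least 3 of 6 libraries were tested (15312 genes), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SEs were computed from the log2 change and the F statistic. At these totals the spread between pools, not counting error, limits the precision: the common biological coefficient of variation was 0.329. No pair of libraries within a group agreed within counting noise, since chi-square per gene was 137 or more in each of the 6 pairs.

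Lists of 23 gene groups and 13 cell types that matched genes in the table, fixed from textbook knowledge before the data were examined, were matched by symbol or by description. A further list, of mitochondrially encoded transcripts, matched 0 genes. Lists with at least 5 tested members entered limma's camera on log2(FPKM + 1), two-sided, with an inter-gene correlation preset to 0.01 and, as an alternative, estimated per list. None of the 18 lists called with the preset value was called with an estimated one. The gene ontology and pathway terms of the table with 10 to 300 tested members were tested in the same way. The genes named follow a rule. It took the 10 largest rises and the 10 largest falls in log2(FPKM + 1) among called genes with a symbol or an informative description, a mean FPKM of at least 5 in the higher group and groups that do not overlap. It added the 4 members of each list with the smallest p and a fixed set of hypoxia, antioxidant, caspase and hemoglobin genes. Outside this rule nfkbia, LOC113643039, LOC113642854, noxo1, LOC113636093, LOC113650706 and lcp1 were chosen after their values were seen. A table of gene names for another assembly, HZAU_Pvac_v1, held 0 of the gene identifiers and was not used here.

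Transcript length was estimated as the median over libraries of the count divided by the FPKM and the library total, scaled to bases, where the count was at least 10. For the length correction a loess curve (span 0.5) of each library's deviation on log2 length entered edgeR as an offset. Random lists for comparison were drawn 10000 times, each member replaced by 1 of the 50 genes nearest to it in length and expression. The genes were drawn singly, so the range of these lists is a spread over genes and not between pools.

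Members of the inflammatory list were tested one-sided against the median of leukocyte markers minus 1 SD over the markers (-0.78), which entered edgeR as an offset of the hypoxia libraries, with Benjamini-Hochberg adjustment over the list.

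The tests were tried on simulated data. In 5 sets of counts drawn for the 15312 genes from their real means, dispersions and library sizes with 200 genes changed, known folds were tried. The test of hypoxia against normoxia recovered 0% of the genes changed 1.5-fold, 10.4% of those changed 2-fold and 84.5% of those changed 4-fold. Of its 341 calls 27 were false, or 7.92%, and with no gene changed it made 1 call over the 5 sets. DESeq2 1.42.0, an alternative, made 716 calls on the same sets with 33.2% false. The real comparison called 1461 genes, down to a log2 change of 0.46 in size. The adjusted threshold depends on the share of genes changed, so the simulated rates of recovery do not carry over to it. A list of 30 genes shifted by 0.5 was called by camera with either correlation, and none of the unshifted lists was. The genes of these simulated lists were drawn independently of each other. In the real lists the estimated correlation ran from -0.05 for neutrophil and granulocyte markers to 0.77 for cytosolic ribosomal proteins. The simulation therefore cannot show how often camera with the preset correlation falsely calls a list whose members vary together. With a simulated trend on length and no change, the median of short genes was 0.52 before the correction and 0.03 after it. For the test against a bound, 99 of 100 genes set 4 below it were recovered, and 2 of 50 lists with every member at the bound held a call.

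Alternatives covered the scaling, the filter, the pseudocount, the variance model, the fold threshold, a replicate block, each library left out, DESeq2 and limma.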

Results

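Messenger RNA of the gill was sequenced from hybrid yellow catfish, the offspring of a Tachysurus fulvidraco mother and a Pseudobagrus vachellii father, after a 96 h trial at a low or an ordinary level of dissolved oxygen. The hypoxia group was held at 1.5 mg/L dissolved oxygen and the control group, called normoxia here, at 6.5 mg/L. Each group had 9 fish, and equal amounts of their RNA were mixed in sets of 3 fish, which gave 3 hypoxia libraries and 3 normoxia libraries. The deposited table held counts and FPKM for 28288 genes in these 6 libraries. Total counts were 55016223, 46885400 and 49424416 in normoxia replicates 1, 2 and 3, and 44762764, 53107146 and 54578326 in hypoxia replicates 1, 2 and 3. Whether a count stands for a read or a read pair is not given in the sources used here.

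The question set by the design was which transcripts of the gill, the organ that takes up oxygen, differ between fish at low and at ordinary oxygen. On log2(FPKM + 1) of the 15312 genes tested, the first principal component carried 44.9% of the variance and separated the groups, with scores of 25.9 to 43.3 for hypoxia and -47.9 to -23.4 for normoxia. Pearson's correlation across genes, which are not independent replicates, was 0.945 to 0.965 for the 6 pairs of libraries within a group and 0.910 to 0.940 for the 9 pairs between groups. Cytosolic ribosomal protein genes took 16.0%, 16.1% and 15.5% of the counts in normoxia replicates 1, 2 and 3, against 23.4%, 19.3% and 16.0% in hypoxia replicates 1, 2 and 3.

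In hypoxia 11 of 23 tested genes of glycolysis were higher, as were 52 of 88 in the list of nuclear-encoded subunits of oxidative phosphorylation. The oxygen-sensing hydroxylase genes egln3 and hif1an were also higher. Among the largest falls were nos2, the gene of inducible nitric oxide synthase, and 2 chemokine genes. The glycolysis and oxidative phosphorylation lists were both called as higher by camera. With an estimated correlation the camera adjusted p = 0.240 for glycolysis and adjusted p = 0.284 for oxidative phosphorylation. Without hypoxia replicate 1 or 2 or normoxia replicate 2 or 3 at most 2 of the 88 oxidative phosphorylation genes were called. Of 15312 genes tested, 825 were higher and 636 lower in hypoxia, together 9.54% of the genes, and of these 287 rose and 362 fell at least 2-fold. The genes past the threshold had a median log2 change of 0.95 in size, against a median SE of 0.21 over all genes. In 5717 genes, or 37.3%, the FPKM of the 2 groups did not overlap. A random split gives 10% on average, but genes vary together, so a single split can lie far from that. The share was counted on FPKM without TMM scaling and was not computed for the other splits. TMM scaling set the balance of the directions: with library totals alone 364 genes were higher and 812 lower, and the median log2 change of all genes moved from -0.04 to -0.20. With limma on the deposited log2(FPKM + 1), which has no TMM scaling, 479 were higher and 887 lower, or 35.1% higher against 56.5% in the main comparison. All changes given here are relative to the TMM centre. FPKM are given as deposited, without this scaling, so the ratio of 2 FPKM means can differ from the change printed beside them. The counts rested on all 6 libraries, with 129 genes higher and 122 lower without hypoxia replicate 1, 130 and 109 without hypoxia replicate 2, and 372 and 259 without hypoxia replicate 3. They were 490 and 422 without normoxia replicate 1, 68 and 64 without normoxia replicate 2, and 95 and 86 without normoxia replicate 3. Of the 74 genes named here that passed, 21 passed in each of these 6 fits: egln3, hif1an, LOC113643564, hk1, pgam1, LOC113646941, LOC113639893, LOC113649352, LOC113647249, LOC113651686, LOC113640651, hspd1, nos2, noxo1, LOC113653320, LOC113636071, LOC113637990, LOC113646793, LOC113639030, LOC113635703 and LOC113635166.

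**Figure D1:**
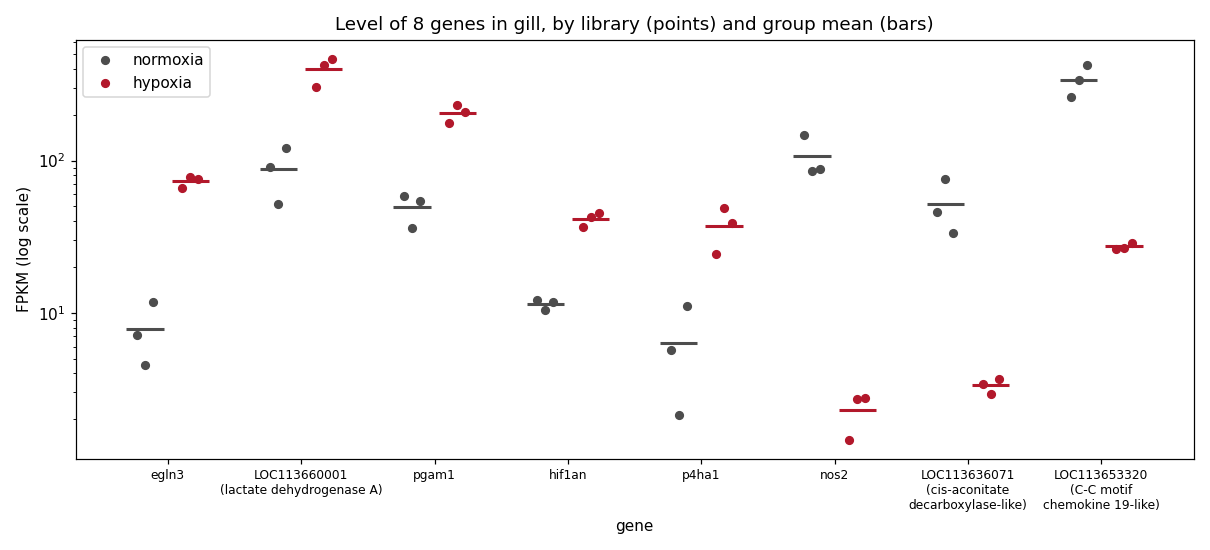
Level in FPKM on a log axis of 8 genes in the 3 normoxia libraries (grey) and the 3 hypoxia libraries (red), with points for libraries and bars for group means. The groups do not overlap in any of the 8 genes, from egln3 at 7.82 and 73.4 to nos2 at 107 and 2.31 FPKM in normoxia and hypoxia.

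The largest rises by the fixed rule included the genes LOC113639893, egln3, LOC113649352 and LOC113651686. LOC113639893, described as a DNA damage-inducible transcript 4 protein-like gene, of the family that inhibits the growth kinase mTOR, rose from 0.645 ± 0.200 to 24.4 ± 1.43 FPKM (mean ± SD), with n = 3 libraries per group here and below. This was a log2 change of 5.40 ± 0.27 (SE) with an edgeR adjusted p of 0.00204. The gene lies on scaffold NW_020848328.1 from 4429885 to 4431663, on the same scaffold as hif1an, at 4460258 to 4472224, which encodes the asparaginyl hydroxylase that inhibits hypoxia-inducible factor and rose 4.03-fold (log2 change 2.01 ± 0.13, edgeR adjusted p = 0.00204). The prolyl hydroxylase gene egln3, whose product marks hypoxia-inducible factor for degradation in the presence of oxygen, lies on scaffold NW_020848035.1 from 6869312 to 6881096. It rose from 7.82 ± 3.67 to 73.4 ± 6.75 FPKM, a log2 change of 3.39 ± 0.34 (edgeR adjusted p = 0.00757). Other rises were in the zinc finger protein gene LOC113649352, by 3.36 ± 0.18, and in the intelectin gene LOC113647249, by 4.71 ± 0.39 on the log2 scale. The usherin-like gene LOC113651686 rose by 5.92 ± 0.49 and p4ha1, a collagen prolyl hydroxylase subunit, by 2.71 ± 0.57. The keratin, type I cytoskeletal 19-like gene LOC113651860 rose from 196 ± 63.9 to 995 ± 351 FPKM, a log2 change of 2.54 ± 0.38. For the fibroblast growth factor-binding protein 1-like gene LOC113660664 and the C-type lectin domain family 4 member E-like gene LOC113643665 the hypoxia libraries varied widely, at 25.1 ± 21.4 and 34.6 ± 23.5 FPKM against 1.79 ± 0.253 and 4.31 ± 1.30 in normoxia. The interferon-induced protein 44-like gene LOC113650707 had counts of 0 in 2 of 3 normoxia libraries and 6.63 ± 3.97 FPKM in hypoxia, and its call ended with the length correction given with the transcript lengths (edgeR adjusted p = 0.0626).

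The 10 largest falls by the fixed rule included the gene of inducible nitric oxide synthase, 2 cis-aconitate decarboxylase-like genes and 2 chemokine genes. The rule ranked called genes by log2(FPKM + 1), so a gene outside it can have a larger fitted fall, as noxo1 did (-6.47 ± 0.59, chosen after its values were seen). The inducible nitric oxide synthase gene nos2, on scaffold NW_020847798.1 from 1349940 to 1358372, fell from 107 ± 34.7 to 2.31 ± 0.734 FPKM, a log2 change of -5.39 ± 0.36 (edgeR adjusted p = 0.00204). The C-C motif chemokine 19-like gene LOC113653320, on scaffold NW_020847937.1 from 2521657 to 2523318, fell from 341 ± 81.3 to 27.3 ± 1.44 FPKM (log2 change -3.48 ± 0.19, edgeR adjusted p = 0.00204). The CC chemokine gene LOC113633925 fell from 32.6 ± 9.45 to 2.61 ± 1.45 FPKM. Of the genes described as cis-aconitate decarboxylase-like, the enzyme that makes itaconate in activated macrophages of mammals, LOC113636071 fell 13.9-fold and LOC113637990 fell 13.4-fold, with log2 changes of -3.80 ± 0.32 and -3.74 ± 0.40. The S100-A5-like gene LOC113646793 fell from 78.0 ± 36.6 to 2.90 ± 0.555 FPKM and the pleckstrin homology domain gene LOC113639030 from 104 ± 50.5 to 8.82 ± 4.51 FPKM. A pair of tripartite motif 35-like genes, LOC113652671 and LOC113652262, fell by 3.95 and 4.03 on the log2 scale with SEs of 0.65 and 0.71. LOC113635703, described as a probable alpha-ketoglutarate-dependent hypophosphite dioxygenase, fell from 95.5 ± 42.6 to 5.07 ± 2.33 FPKM. Reads of the decarboxylase-like, tripartite motif 35-like and interferon-induced protein 44-like genes could be split between close copies, so their single values are uncertain.

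Of 23 tested genes of glycolysis 11 were higher and none lower (12 and 0 adjusted over the list alone), 16 had a log2 difference above 0, and the median was 0.88. Camera gave the list an adjusted p of 2.67e-07, and an adjusted p = 0.240 with an estimated correlation. Hexokinase hk1 rose from 18.1 ± 0.790 to 42.8 ± 0.656 FPKM (log2 change 1.40 ± 0.13, edgeR adjusted p = 0.00509). Phosphoglycerate mutase pgam1 rose from 49.5 ± 11.9 to 206 ± 27.9 FPKM (log2 change 2.21 ± 0.23), the aldolase C gene LOC113646941 by 1.98 ± 0.22 and the monocarboxylate transporter slc16a3, which exports lactate, by 1.95 ± 0.24. The L-lactate dehydrogenase A gene LOC113660001 rose 5.03-fold with TMM scaling (edgeR adjusted p = 0.0159). Its deposited levels were 87.7 ± 34.5 FPKM in normoxia and 398 ± 83.9 FPKM in hypoxia. The list's mean level lay above the highest normoxia library in 2 of 3 hypoxia libraries. Its count of members called higher ran from 4 without normoxia replicate 3 to 10 without normoxia replicate 1, with 5 without hypoxia replicate 2 and 6 without normoxia replicate 2.

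Of 22 tested genes of the hypoxia-inducible factor pathway and its targets, 4 rose, namely egln3, hif1an, the egln2-like gene LOC113643564 (1.83 ± 0.13) and p4ha1, and 1 fell. The counts were 4 and 1 adjusted over the list alone. With 1 library left out 3 rose in each of the 6 fits, since p4ha1 lost its call in all of them, and bnip3, the member that fell, was called only without normoxia replicate 1. The call of p4ha1 was also lost in edgeR without an abundance trend (adjusted p = 0.0557). The list names ddit4 by symbol only, so the DNA damage-inducible transcript 4 protein-like gene LOC113639893, which rose, is not counted in it. For the rise of the list the camera adjusted p was 0.00524, with an adjusted p = 0.340 with an estimated correlation. The mitophagy receptor bnip3 fell from 4.19 ± 0.670 to 1.57 ± 0.176 FPKM (log2 change -1.25 ± 0.21, edgeR adjusted p = 0.0240). Transcripts of the factor subunits did not pass the test: hif1a had a log2 difference of -0.19 ± 0.13 epas1 of -0.01 ± 0.19, of either sign under other scalings, and the hypoxia-inducible factor 1-alpha-like gene LOC113662105 of -0.45 ± 0.39. The value of vegfa was 1.28 ± 0.55 (edgeR adjusted p = 0.169), at 1.01 ± 0.643 and 2.21 ± 0.764 FPKM. The more abundant vascular endothelial growth factor A-A-like gene LOC113637314, at 5.50 ± 0.928 and 5.10 ± 1.22 FPKM, had a log2 difference of 0.04 ± 0.24 (edgeR adjusted p = 0.926), of either sign under other scalings. No tested gene had the symbol slc2a1, and the glucose transporter member 1-like gene LOC113643039 had a log2 difference of 0.46 ± 0.17 (edgeR adjusted p = 0.118) and the like gene LOC113642854 of -0.48. The insulin-like growth factor-binding protein 1 gene was under the FPKM filter. None of the 9 hemoglobin genes passed the test, with log2 differences from -0.58 to 0.12 and a smallest edgeR adjusted p of 0.211, and they are close copies that can share reads.

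**Figure D2:**
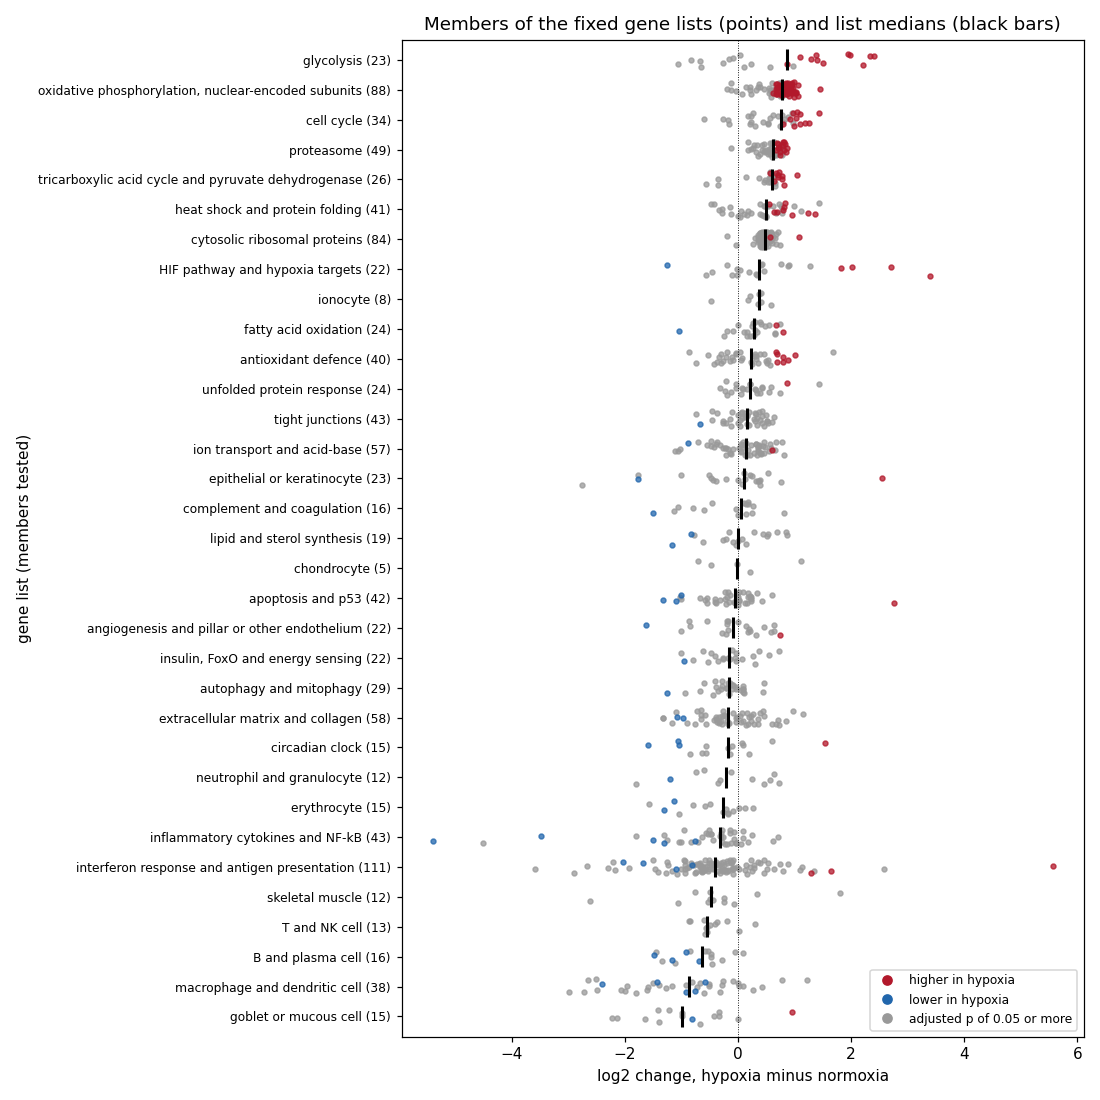
Log2 change between hypoxia and normoxia for each tested member (points) of the fixed gene lists and cell type marker lists with at least 5 tested members, and the list median (black bars). Points are red for members higher in hypoxia, blue for members lower and grey for those past no threshold. The list medians run from 0.88 for glycolysis to -0.98 for goblet or mucous cell markers.

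Of 88 tested genes in the list of nuclear-encoded subunits of oxidative phosphorylation 52 were higher and none lower (75 and 0 adjusted over the list alone). The median log2 change was 0.78. The list takes all symbols that start with ndufa, which can include assembly factors, and it names the electron carrier cycs. Not every member need therefore be a subunit. Camera gave adjusted p = 2.82e-32, and adjusted p = 0.284 with an estimated correlation. The list mean lay above the highest normoxia library in 3 of 3 hypoxia libraries. The cytochrome b-c1 complex subunit 9 gene LOC113646590 rose from 196 ± 7.33 to 333 ± 7.64 FPKM (log2 change 0.93 ± 0.13, edgeR adjusted p = 0.0159). The ATP synthase subunit atp5po rose from 202 ± 20.4 to 352 ± 18.3 FPKM and the cytochrome c oxidase subunit 7A2 gene LOC113659295 from 64.6 ± 8.13 to 110 ± 1.52 FPKM. The single calls depended on the libraries, with 46 members higher without hypoxia replicate 3 and 41 without normoxia replicate 1. There were 2 without hypoxia replicate 1, 1 without normoxia replicate 2 and 0 without hypoxia replicate 2 or normoxia replicate 3, and 14 with the length correction given with the transcript lengths. Of 26 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 10 rose and none fell (21 and 1 adjusted over the list alone), among them mdh2 (1.05 ± 0.19), sdha (0.73 ± 0.13) and the pyruvate carrier subunit mpc2 (0.82 ± 0.12). The camera adjusted p was 7.64e-10, with an adjusted p = 0.284 with an estimated correlation. That list had 8 members called without hypoxia replicate 3 or normoxia replicate 1, 1 without hypoxia replicate 2 and 0 without hypoxia replicate 1, normoxia replicate 2 or normoxia replicate 3. Of 24 genes of fatty acid oxidation 2 rose, the electron transfer flavoprotein subunits etfb and etfa, and 1 fell, the adipogenic receptor pparg (-1.03 ± 0.19), against 7 and 1 adjusted over the list alone. The call of etfa ended with the length correction, where its log2 change was 0.51, and was kept in 0 of the 6 fits without 1 library. Of that list 2 members were called higher without hypoxia replicate 3, 1 without normoxia replicate 1 and 0 in the other 4 fits, and the fall of pparg was called only without normoxia replicate 3. The camera adjusted p of that list was 0.00913, with adjusted p = 0.432 with an estimated correlation. It was 0.0518 without hypoxia replicate 2, the highest of the list's 15 alternatives with the preset correlation.

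Of 49 proteasome genes 15 rose and none fell (36 and 0 adjusted over the list alone), with a median log2 change of 0.61 and for psmb6 a level of 106 ± 13.7 in normoxia and 173 ± 13.7 FPKM in hypoxia. Camera gave that list adjusted p = 1.35e-15, and adjusted p = 0.357 with an estimated correlation. Its members called higher were 12 without normoxia replicate 1, 3 without hypoxia replicate 3, 0 without hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 2 or normoxia replicate 3, and 2 with the length correction. Of 84 cytosolic ribosomal protein genes only 2 passed the test, both higher, against 1 adjusted over the list alone. They were rpl22l1 (1.07 ± 0.15) and the 60S ribosomal protein L7-like 1 gene LOC113637387 (0.57 ± 0.12). Both are described as like a ribosomal protein, and no other member was called. The call of LOC113637387 ended with the length correction, where its log2 change was 0.48 (edgeR adjusted p = 0.0538). With 1 library left out LOC113637387 was called in 0 of the 6 fits and rpl22l1 in 3, those without normoxia replicate 1, hypoxia replicate 1 or hypoxia replicate 3. In all 82 members had a log2 difference above 0 with a median of 0.48. That median was 0.13 with the length correction, just inside the upper end of the central 95% of random lists matched on length and expression (-0.15 to 0.13). Camera gave adjusted p = 9.88e-15, with adjusted p = 0.480 with an estimated correlation and 0.0930 after quantile normalization, and the list mean lay above all normoxia libraries in 2 of 3 hypoxia libraries. Of 41 genes of heat shock and protein folding 9 rose and none fell (18 and 0 adjusted over the list alone). They included the mitochondrial chaperonins hspd1 (1.25 ± 0.12) and hspe1 (1.36 ± 0.23), the mitochondrial chaperone hspa9 (0.69 ± 0.12) and the chaperonin subunit cct7 (0.95 ± 0.19). With 1 library left out 6 members were called without hypoxia replicate 3, 5 without normoxia replicate 1 and 1 without hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 2 or normoxia replicate 3. The list had a camera adjusted p of 1.01e-07 and an adjusted p = 0.240 with an estimated correlation. Of 24 genes of the unfolded protein response only the asparagine synthetase gene asns passed, also adjusted over the list alone, at 0.87 ± 0.18, and with 1 library left out it passed only without normoxia replicate 1. The list's camera adjusted p of 0.0455 became 0.181 without normoxia replicate 2 and 0.116 without hypoxia replicate 3, with adjusted p = 0.649 with an estimated correlation. After quantile normalization it was 0.407, the highest of the list's 15 alternatives with the preset correlation.

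Cell cycle genes rose in 11 of 34 members, with none lower (20 and 0 adjusted over the list alone) and a median log2 change of 0.76. The mitotic cyclin ccnb2 rose by 1.44 ± 0.27, from 8.21 ± 2.39 to 20.2 ± 5.13 FPKM (edgeR adjusted p = 0.0305). The kinase cdk1, which drives entry into mitosis, rose by 1.25 ± 0.24, from 44.6 ± 10.6 to 95.4 ± 21.7 FPKM (edgeR adjusted p = 0.0307). The members called were 8 without normoxia replicate 1, 1 without hypoxia replicate 1 or 3, and 0 without hypoxia replicate 2 or normoxia replicates 2 or 3. Camera gave adjusted p = 1.81e-09, and adjusted p = 0.418 with an estimated correlation. Of 40 genes of antioxidant defence 7 rose and none fell (9 and 0 adjusted over the list alone), including the microsomal glutathione transferase mgst3 (1.01 ± 0.12) and the mitochondrial peroxiredoxin prdx3 (0.80 ± 0.14). The members called were 6 without hypoxia replicate 3, 5 without normoxia replicate 1, 1 without hypoxia replicate 1 or 2, and 0 without normoxia replicate 2 or 3. The camera adjusted p was 0.0113, with adjusted p = 0.340 with an estimated correlation. It was 0.0730 without hypoxia replicate 2 and 0.493 after quantile normalization, the highest of the list's 15 alternatives with the preset correlation. The superoxide dismutase sod1 rose from 114 ± 10.8 to 189 ± 24.2 FPKM (edgeR adjusted p = 0.0234, and 0.0531 with the length correction). Catalase, cat, was at 13.9 ± 1.61 and 12.0 ± 3.61 FPKM (log2 difference -0.03 ± 0.26), of either sign under other settings.

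Of 43 tested genes of the inflammatory list 5 were lower and none higher, both over all genes and adjusted over the list alone. Camera gave adjusted p = 0.000367, and adjusted p = 0.240 with an estimated correlation. Beside nos2 and LOC113653320 these were the C-X-C motif chemokine 11-like gene LOC113637706 (-1.49 ± 0.30) and the inhibitors of NF-kappa-B nfkbie (-0.76 ± 0.13) and nfkbia, which fell from 339 ± 49.6 to 121 ± 30.2 FPKM (-1.30 ± 0.27). These inhibitors are themselves induced by NF-kappa-B. Members called lower were 4 without normoxia replicate 1 or hypoxia replicate 3, 3 without normoxia replicate 2 or 3, and 2 without hypoxia replicate 1 or 2. In the list of interferon response and antigen presentation 3 of 111 members rose and 4 fell (0 and 1 adjusted over the list alone), among them ifih1, a cytosolic sensor of viral RNA (-1.09 ± 0.17). Members called lower ran from 4 without hypoxia replicate 1 to 0 without normoxia replicate 3, and 1 was called higher without normoxia replicate 1 and 0 in the other 5 fits. The camera adjusted p for a fall of that list was 0.00904, with adjusted p = 0.340 with an estimated correlation. It was 0.0839 without hypoxia replicate 3 and 0.172 with members matched by symbol only, the highest of the list's 15 alternatives with the preset correlation. Of 16 complement and coagulation genes 1 fell, the urokinase gene plau (-1.50 ± 0.18), whose call was lost without normoxia replicate 2 or 3, and the list did not pass (camera adjusted p = 0.570).

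The marker lists of B and plasma cells, macrophages and dendritic cells, and T and NK cells were called lower by camera, with few members called and adjusted p = 0.340 for each with an estimated correlation. The B and plasma cell list had 2 members called without normoxia replicate 1 and 1 without hypoxia replicate 3. It had 0 without normoxia replicate 2 or 3 or hypoxia replicate 1 or 2. The macrophage list had 3 called without hypoxia replicate 3, 0 without normoxia replicate 3 and 1 without any other single library. Of 16 B and plasma cell markers 4 fell and none rose, also adjusted over the list alone, including btk (-1.17 ± 0.20), cd79a (-1.49 ± 0.31) and blnk (-0.69 ± 0.14). The list had a median log2 change of -0.64, a camera adjusted p of 0.00125 and adjusted p = 0.340 with an estimated correlation. Of 38 macrophage and dendritic cell markers 5 fell and none rose (6 and 0 adjusted over the list alone), including the macrophage-expressed gene 1-like gene LOC113656273 (-0.92 ± 0.12) and the myeloid factor spi1 (-0.59 ± 0.14). The list had a median of -0.87 and a camera adjusted p of 0.000368, and adjusted p = 0.340 with an estimated correlation. That list consists largely of genes described as macrophage mannose receptor 1-like. Its adjusted p was 0.258 with the 9 members matched by symbol only, the highest of its 15 alternatives with the preset correlation. None of the 13 T and NK cell markers passed over all genes, and 7 passed as lower adjusted over the list alone. The median was -0.55, with a camera adjusted p of 0.00542 and adjusted p = 0.340 with an estimated correlation. Of 12 members of the neutrophil and granulocyte list the myeloperoxidase gene LOC113661326 was lower (-1.21 ± 0.27, edgeR adjusted p = 0.0423, and 0.0575 with the length correction). That call was lost without any 1 of the 6 libraries, and the list did not pass (camera adjusted p = 0.781). Its match by description also took in a leukocyte elastase inhibitor gene, LOC113634349 (0.45 ± 0.16), which is not elastase itself. The list median was -0.22, and that of the 8 members matched by symbol was -0.33.

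Of 15 goblet or mucous cell markers, mostly mucin-5AC-like genes, 1 rose and 1 fell, with a median of -0.98, the lowest of the lists tested, and a camera adjusted p of 0.0370, and adjusted p = 0.649 with an estimated correlation. With 1 library left out 1 member was called higher without normoxia replicate 1 and 0 were called in the other 5 fits. The camera adjusted p became 0.114 without hypoxia replicate 1 and 0.115 without normoxia replicate 2. With members matched by symbol only it was 0.553, the highest of the list's 15 alternatives with the preset correlation. Erythrocyte markers fell in 2 of 15, hemgn (-1.30 ± 0.30) and gypc (-1.12 ± 0.24, edgeR adjusted p = 0.0636 with the length correction). With 1 library left out 3 members were called without normoxia replicate 1 and 0 in the other 5 fits. The list did not pass by camera (adjusted p = 0.137), although its median of -0.26 lay below that of random lists matched on length and expression. It passed in 3 of its 15 alternatives with the preset correlation, among them without normoxia replicate 1 (0.00121) and after quantile normalization (0.00538). Over these 15 its adjusted p ran from 0.00121 to 0.421, and with an estimated correlation the camera adjusted p was 0.717. Ionocyte markers, 8 genes of the ion-transporting cells of the gill, did not pass (median 0.37, camera adjusted p = 0.142, 0 members called). Nor did those of epithelial or keratinocyte cells (0.655), chondrocytes (0.574) or skeletal muscle (0.700), whose median of -0.47 differed in sign from its camera direction. The chondrocyte list passed as higher with no expression filter (0.0286), the lowest of its 13 alternatives with the preset correlation, which reached 0.931. Epithelial markers held opposite calls, as LOC113651860 rose and another keratin 19-like gene, LOC113657902, fell (-1.76 ± 0.27). No epithelial marker was called without normoxia replicate 2 or hypoxia replicate 2. The smooth muscle and neuron lists had 4 tested members each, none of them called, and no liver marker passed the expression filter.

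Of the remaining lists, autophagy and mitophagy had 1 of 29 members lower, bnip3, also adjusted over the list alone, a call kept only without normoxia replicate 1 among the fits without 1 library. Its camera adjusted p of 0.0335 became 0.0558 without normoxia replicate 1, 0.0693 without normoxia replicate 2 and 0.101 without hypoxia replicate 3, and adjusted p = 0.475 with an estimated correlation. With median-of-ratios scaling it was 0.145, the highest of the list's 15 alternatives with the preset correlation. The circadian clock list had 1 member higher and 3 lower of 15 and did not pass (camera adjusted p = 0.266). Its calls were the period 2-like genes LOC113640651 (1.53 ± 0.15) and LOC113640397 (-1.06 ± 0.16), per3 (-1.04 ± 0.17) and nr1d1 (-1.58 ± 0.37, edgeR adjusted p = 0.0757 with the length correction). LOC113640651 was called in each fit without 1 library, and the members called lower were 2 without normoxia replicate 1, 0 without normoxia replicate 2 or hypoxia replicate 1, and 1 in the other 3 fits. In apoptosis and p53, 1 of 42 members rose, the caspase-3-like gene LOC113639256 (2.75 ± 0.48), and 3 fell (1 and 4 adjusted over the list alone). Among those that fell were gadd45a (-1.32 ± 0.19) and the caspase-4-like gene LOC113635166, from 36.8 ± 1.66 to 16.5 ± 2.18 FPKM. LOC113639256 was called only without hypoxia replicate 3 among the fits without 1 library, and 1 or 2 members were called lower in each. The camera adjusted p of the list was 0.279. The other caspase-3-like genes, LOC113635854 at 0.61 and LOC113635419 at -0.23, and casp9 at -0.19 ± 0.15 did not pass. Ion transport and acid-base (0.520), tight junctions (0.209), extracellular matrix and collagen (0.810), lipid and sterol synthesis (0.810), angiogenesis and endothelium (0.861) and insulin, FoxO and energy sensing (0.208) did not pass by camera adjusted p. Without normoxia replicate 1 the tight junction list passed as higher (0.0213) and the matrix list as lower (0.0412). The median and the mean of the complement and coagulation, epithelial, chondrocyte, and lipid and sterol lists differed in sign, and the angiogenesis list had a median of -0.08 with a camera direction upward. With library totals the medians of the complement, ion transport, tight junction and epithelial lists were under 0, and with median-of-ratios scaling those of the lipid and sterol and chondrocyte lists were over 0.

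Of 1479 gene ontology and pathway terms in the authors' annotation, 152 were higher and 53 lower by camera, while with an estimated correlation no term passed and the smallest adjusted p = 0.964. Among the highest ranked were oxidative phosphorylation (63 of 128 members higher, adjusted p = 1.81e-26), the ribosome (29 of 106, 1.83e-24) and translation (48 of 252, 1.69e-16). Among those that fell were G-protein coupled receptor signalling (22 of 233 members lower, adjusted p = 0.000116), Jak-STAT signalling (13 of 174, 0.000317), chemotaxis (4 of 48, 0.000927) and NF-kappa B signalling (9 of 44, 0.00226).

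Changes also followed transcript length. In 20 bins of equal gene number the median log2 change fell from 0.32 in the shortest transcripts, with a median length of 603 bases, to -0.29 in the longest, with a median of 8439 bases. Spearman's rho across genes, which are not independent replicates, was -0.255. The slope of log2 level on log2 length was 0.06, 0.09 and 0.04 in normoxia replicates 1, 2 and 3, and -0.11, -0.09 and 0.01 in hypoxia replicates 1, 2 and 3. The oxidative phosphorylation genes had a median length of 711 bases, the ribosomal protein genes 638 and the proteasome genes 1247, against 2570 over the genes tested. The medians of the antioxidant, unfolded protein response and autophagy lists lay inside the central 95% of random lists matched on length and expression, but with the length correction described next that of the autophagy list, -0.19, lay below it. The erythrocyte and neutrophil lists, which did not pass by camera, had medians below such lists, at -0.26 against 0.05 to 0.51 and at -0.22 against -0.09 to 0.53. They stayed below with the correction, at -0.64 and -0.29, and the skeletal muscle median, inside without it, was then below at -0.61. When each library was corrected for its trend with length, an alternative chosen after seeing the data, 541 genes were higher and 390 lower, of which 844 had also passed without the correction.

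**Figure D3:**
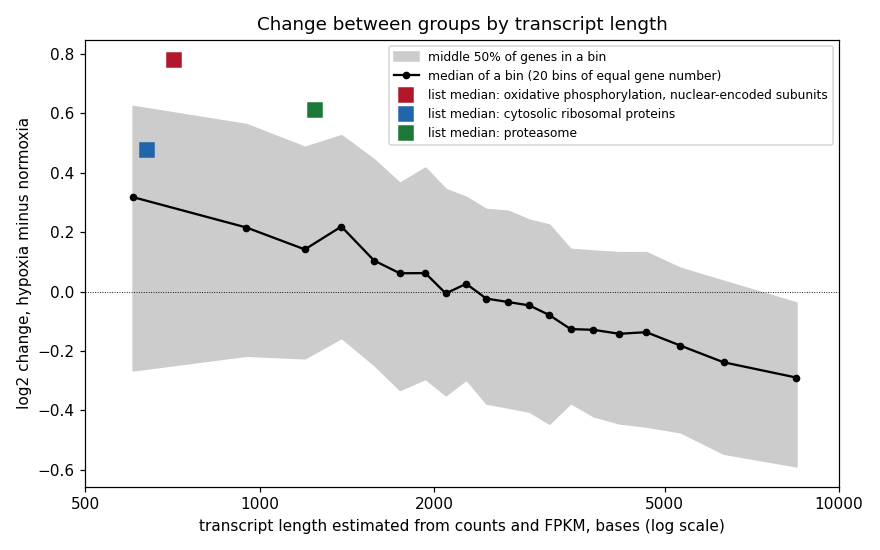
Median log2 change between hypoxia and normoxia (black line) and the middle 50% of genes (grey) in 20 bins of transcript length, which is on a log axis and was estimated from the deposited counts and FPKM, with the medians of 3 gene lists as squares. The bin medians fall from 0.32 to -0.29, and the list medians of 0.78 for oxidative phosphorylation, 0.48 for ribosomal proteins and 0.61 for the proteasome lie above the line.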

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

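The length correction, the library totals and the list test on TMM-scaled counts were alternatives chosen after seeing the data, and the other alternatives were planned. No gene called in the comparison had the other sign under any alternative, those that left out a library included. The counts of 825 genes higher and 636 lower became 541 and 321 with no expression filter, 410 and 369 in edgeR without an abundance trend, 1792 and 1540 with DESeq2, 287 and 362 with a log2 change of at least 1, and 541 and 390 with the length correction. With library totals they were 364 and 812. In limma on the deposited FPKM they were 479 and 887 with a trend, 364 and 814 without it, 490 and 918 in the robust fit, 436 and 748 with a pseudocount of 0.1, and 452 and 824 with 0.5. The share of higher genes was thus 30.9% to 36.8% in these limma fits, against 56.5% in the main comparison. With scaling added to limma the counts were 917 and 613 (59.9% higher) with median-of-ratios, 757 and 774 (49.4%) with upper-quartile and 669 and 482 (58.1%) with quantile normalization, so the balance moved with the scaling. Without 1 library the higher genes ran from 68 to 490 and the lower from 64 to 422. The stricter fold threshold removes calls by its definition. The fits without 1 library all had the same number of libraries, so that number does not explain the range between them. The cause of the other changes was not tested.

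Of the fixed lists 11 were higher and 7 lower, and of the terms 152 and 53; with an estimated correlation 0 lists and 0 terms were called in either direction, and 4 lists were lower with members matched by symbol only. Single values with differences near 0 changed sign without passing the threshold. For epas1 the log2 difference was 0.0346 with no filter, 5.77e-05 with median-of-ratios scaling, 0.0234 with that scaling in limma, 0.00724 with the replicate block, 4.80e-05 with DESeq2, 0.23 with the length correction, and -0.16 to 0.19 without 1 library. For cat it was 0.0169 with no filter, 0.0269 with the length correction and -0.27 to 0.21 without 1 library. For LOC113637314 it was -0.0328 with the stricter filter, -0.10 in limma with or without a trend and in the robust fit, -0.12 and -0.11 with pseudocounts of 0.1 and 0.5, -0.0172 with upper-quartile scaling in limma, -0.12 with library totals, -0.13 with the length correction and -0.0842 to 0.16 without 1 library. Without 1 library it was -0.52 to 0.0537 for LOC113635419 and -0.20 to 0.0526 for lcp1.

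The replicate numbers are shared by the groups, but deviations from the group means correlated at -0.04, 0.02 and -0.06 for numbers 1, 2 and 3, so the numbers were not read as pairs. Not every sample correlated best with its own number, as hypoxia replicate 3 did so with normoxia replicate 1 (0.09). With the number as a replicate block 122 genes were higher and 120 lower, and the erythrocyte list was called lower (camera adjusted p = 0.0451).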

Other observations

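All choices of genes in this paragraph were made after their values were seen. Neighbouring or similarly described genes were called in opposite directions. The interferon-induced protein 44-like genes LOC113650707 and LOC113650706 lie on the same scaffold, from 51087 to 55108 and from 90431 to 94453. The former rose, while the latter fell from 45.9 ± 4.79 to 10.4 ± 6.73 FPKM (log2 change -2.03 ± 0.49, edgeR adjusted p = 0.0478). With the length correction the log2 change of the latter was -2.23, no smaller in size, and its call was lost (edgeR adjusted p = 0.0544). With 1 library left out each gene of the pair was called in 1 of the 6 fits. On scaffold NW_020848201.1, 3 genes that fell lie close together: LOC113635703 from 14272645 to 14275656, and the cis-aconitate decarboxylase-like genes LOC113636093 from 14313907 to 14317645 and LOC113636071 from 14352653 to 14356708. LOC113636093 fell by 3.51 ± 0.53 on the log2 scale (edgeR adjusted p = 0.0198). The gene noxo1, whose product organizes an NADPH oxidase that makes superoxide, fell from 8.04 ± 4.49 to 0.0792 ± 0.0304 FPKM, a log2 change of -6.47 ± 0.59 (edgeR adjusted p = 0.00509).

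In the paragraphs that follow, the length correction, the test of ribosomal protein genes without hypoxia replicate 1 and the tests of the inflammatory list against leukocyte markers were chosen only after the result was seen. All patterns were found in the same data they were tested on.

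The lists of oxidative phosphorylation and the proteasome were called higher in hypoxia (adjusted p = 0.284 and adjusted p = 0.357 with an estimated correlation), and their transcripts are short, a class that was higher as a whole. After each library was corrected for its trend with length, the list median was 0.48 for oxidative phosphorylation, with 14 members called, and 0.47 for the proteasome, with 2 called. Random lists matched on length and expression had central 95% ranges that ended at 0.22 and 0.29. This argues against length as the whole cause for these lists, although length may account for part of the change. Those ranges give a spread over genes drawn singly, not between pools for members that vary together (estimated correlations 0.36 and 0.57). Variation between pools therefore stays open as a source of the rest. Hypoxia replicate 1 alone does not account for these lists, whose medians without it were 0.67 and 0.60, with both remaining hypoxia libraries above all normoxia libraries. A difference in RNA integrity or library preparation between the groups, and a biological change in short transcripts, both stay open as sources of the length trend.

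For ribosomal proteins the median went from 0.48 to 0.13 with the length correction. It lay just inside the central 95% of random lists (-0.15 to 0.13), of which 349 of 10000 reached it. Length is thus a candidate explanation there, on a borderline outcome. Without hypoxia replicate 1 the median was 0.26. The mean level in hypoxia replicate 3, 0.05 above the normoxia mean on the log2 scale, lay within the normoxia range of -0.05 to 0.05, so this list may rest on hypoxia replicates 1 and 2.

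A hypothesis was that the rise in subunits of oxidative phosphorylation belongs to a broader rise of nuclear genes for mitochondrial proteins. Mitochondrial ribosomal proteins, 74 tested genes in none of the fixed lists, had a median log2 change of 0.66, with 73 above 0, 33 called higher and 0 lower. None of 10000 random lists matched on length and expression reached that median. After the length correction the median was 0.43, against an upper end of 0.12 for random lists, as the hypothesis predicts. The proteasome list, which is not mitochondrial, also lay above its random lists after the correction (0.47 against 0.29). The result thus does not tell a rise of genes for mitochondrial proteins from a wider one. For the terms of the mitochondrial small and large ribosomal subunits the camera adjusted p was 0.964 with an estimated correlation.

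The fall of immune genes could come from fewer leukocytes in the tissue. Of 27 pan-leukocyte marker symbols listed before the test 9 were tested, with a median log2 change of -0.42 (SD over markers 0.37), 8 below 0 and 2 called lower. Their changes ran from -0.83 to 0.46. The abundant plastin gene lcp1, at 350 and 295 FPKM in normoxia and hypoxia, had the smallest change in size of these markers (-0.08 ± 0.19). The marker spi1 is also in the fixed macrophage list. The 43 members of the fixed inflammatory list had a median of -0.32, within that SD of the markers, so fewer leukocytes stay open for the list as a whole. Of its members 2, nos2 and LOC113653320, lay below the marker median by more than that SD (one-sided edgeR test, adjusted p = 3.21e-05 for each over the list alone). They did so with any 1 library left out, against the same bound, which was held fixed without an error of its own. These 2 genes thus fell further than the markers tested. The test was chosen after their falls were seen, so it does not settle whether a loss of leukocytes caused them. The genes noxo1, LOC113636071, LOC113637990 and LOC113636093 were picked for their falls, so their place below the markers decides nothing, and loss of a small cell population and lower expression per cell were not tested and stay open.

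Across the 10 ways to split the 6 libraries into 3 and 3, the real split gave 1461 changed genes and the highest of the others 2, and 1 split, the real one, reached the real count. With 10 splits a share under 0.05 cannot be had.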
